A study of Homo sapiens with 9 samples.

How the data were processed

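RNA-seq of U251 glioblastoma cells was analysed in 3 control and 3 MSI1 knockdown samples, and MSI1 iCLIP in 3 samples of control cells. Groups and replicate numbers came from the sample titles. The protocol text in the labels describes iCLIP and is attached to the RNA-seq samples as well. It does not say how MSI1 was knocked down or what the control cells received, and says that biological replicates were combined for sequencing, while the sample titles and separate values give 3 replicates per group. The aligner, the counting tool, its strand setting and the peak caller are not given in the sources used here. The genome build is hg18, per the submitters' processing notes, and coordinates are printed as the files give them, counted from 1.

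For RNA-seq the authors deposited raw counts of reads per gene, for the same 20848 genes in each sample, and raw counts per exon, for the same 206550 exons. Gene counts summed to between 32919299 and 47277016 per library and exon counts to between 41850423 and 60776151. The exon sums exceed the gene sums, so a read can be counted in more than 1 exon. No exons of 1 gene overlapped, and 1005 exons shared an interval with an exon of another gene. Since the strand setting is unknown, reads of genes that overlap on opposite strands cannot be assigned with certainty. For iCLIP the authors deposited lists of single-nucleotide sites with a strand, a gene symbol and a p-value per site, 1 list per sample. These p-values reach 1 (8.33%, 16.1% and 14.7% of sites in replicates 1, 2 and 3), so the lists had not been limited to low values. They are the authors' own and were used only to limit sites within a list.

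Gene counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM normalisation and the filter filterByExpr, which kept 13856 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design held the group alone, with 4 residual degrees of freedom. Normalised expression is edgeR's CPM with TMM factors, and mean log2 values use a prior count of 2. Gene lists were 31 sets of genes fixed before the data were examined, of which 30 had at least 5 tested members. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, 1 way. Exon counts were tested with edgeR's diffSpliceDGE, each exon against the other exons of its gene, with Simes p-values per gene. Exon shares are an exon's count as a percentage of the counts of the tested exons of its gene.

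Whether replicate numbers pair the samples was checked. The deviations of same-numbered control and knockdown libraries from their group means correlated at 0.32, 0.73 and 0.75 for replicates 1, 2 and 3, all above the bound of 0.1, so the numbers, which come from the titles, were taken to pair the samples and values with the replicate number as a block (2 residual degrees of freedom) are given where they change a call. Control replicate 1 correlated more with knockdown replicate 2 (0.49) than with its own number. No pair of libraries agreed within sampling noise: chi-square per gene, over genes with a summed count of at least 20, was 22.7 or more for each pair.

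iCLIP sites were called shared when the same nucleotide and strand was in all 3 lists (bedtools 2.31.1), and were assigned to exons and introns of the deposited exon tables. Shared positions were compared with 100 shuffles within genes. Genes with an exonic shared site were compared with 10000 random gene sets matched in 10 bins of expression and 5 bins of exonic length, two-sided, and exons with sites within 500 nucleotides were compared likewise. A search for 7-nucleotide words in 3′ UTRs was not part of the design and was added later. It used 12668 tested genes (91.4%) matched by symbol to a 3′ UTR of at least 100 nucleotides in GENCODE release 29 (GRCh38), from which no coordinates were taken. The score of a word is its regression coefficient on the blocked log2 fold change over its standard error, adjusted for 3′ UTR length, GC content and expression, and 100 shuffles over genes gave the range without a relation.

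Genes named in the text follow a rule set before the data were examined. It takes MSI1 and MSI2, the 8 largest rises and 8 largest falls among called genes with mean log2 CPM of at least 2 and groups that do not overlap, up to 4 members of each list by adjusted p, the 10 genes with the most shared iCLIP sites, and up to 5 called iCLIP genes in each direction. It also takes up to 5 exons per direction, of which 0 qualified. Genes outside the rule are named as chosen after their values were seen.

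The tests of genes, exons, gene lists, iCLIP genes among changed genes and 3′ UTR words were tried on simulated data, and the others were not. For genes changed, drawn from the real means over 13709 genes, the unblocked test recovered 86.2% of 4-fold, 25.8% of 2-fold and 0% of 1.5-fold changes with 5 false calls. The blocked test, over 13748 genes, recovered 98.5%, 78.5% and 40.3% with 13 false calls. Each gene test was tried on counts with the spread of its own design, and only those of the blocked test held replicate effects. The gene rates therefore do not compare the tests, and the unblocked gene test was not tried on counts with replicate effects. For exons changed, over 29266 exons, the unblocked test recovered 80% of 4-fold and 2% of 2-fold reductions with 1 false call, and the blocked test 99% and 78% with 55. For gene lists the 1 shifted list and no other was called. Its genes were drawn independently, so it could not show false calls that arise when genes of a list vary together. The matched comparison called 5 of 100 sets without a link and 100 of 100 with one, over 12084 genes. The planted link was stronger than the one found among all changed genes, so how often a weaker link is called was not tried. The word search ranked 18 of 20 planted words first. Alternatives tried were DESeq2 1.42.0 and its size factors, limma-voom, other filters, a fold limit of 1.5, the block, each library left out, other site sets and no matching. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest. Sequence motifs at the iCLIP sites were not analysed here, since no hg18 genome was used.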

Results

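U251 cells, a human glioblastoma line, were studied to learn how gene expression and splicing change when the RNA-binding protein Musashi1 (gene MSI1) is knocked down, and how those changes relate to the RNA positions that MSI1 binds. The 9 samples form 3 groups of 3. RNA-seq was done on 3 control samples, titled WT, and 3 MSI1 knockdown samples, and iCLIP, which maps single nucleotides crosslinked to a protein by ultraviolet light, was done on 3 samples of cells also titled WT with an antibody against MSI1. Gene counts summed to 47277016, 38494503 and 32919299 in control replicates 1, 2 and 3, and to 42427430, 37082699 and 38761198 in knockdown replicates 1, 2 and 3. The iCLIP lists of replicates 1, 2 and 3 held 1746795, 145718 and 208722 sites. Beyond the replicate numbers in the labels, nothing states that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

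MSI1 itself was lower in each knockdown library than in each control library. MSI1 lies on chromosome 12 at 119263516 to 119291341 on the minus strand (hg18). Its raw counts were 726, 688 and 244 in control replicates 1, 2 and 3 and 134, 195 and 90 in knockdown replicates 1, 2 and 3. Normalised expression was 13.8 ± 5.42 CPM (counts scaled by library size, edgeR's cpm; SD, n = 3) in controls and 3.51 ± 1.46 (SD, n = 3) in knockdowns, a log2 fold change of −1.97 with a standard error of 0.42. MSI2, the paralog of MSI1, on chromosome 17 at 52688930 to 53112298, was at 48.1 ± 6.82 CPM in controls and 47.8 ± 1.14 in knockdowns (log2 fold change −0.01, adjusted p = 0.989 by edgeR's quasi-likelihood test). For the MSI1 transcript the same test gave an adjusted p of 0.0699, which missed the threshold of 0.05. With the replicate number as a block the adjusted p was 0.00279, with DESeq2 it was 8.78e-05, and without control replicate 3, the control with the lowest MSI1 level, it was 0.000372 (log2 fold change −2.21).

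**Figure D1:**
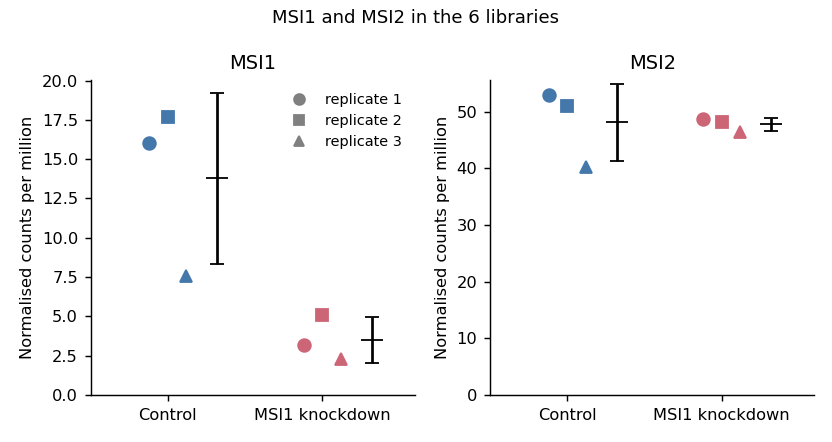
Normalised CPM (vertical axes) of MSI1 and MSI2 in 3 control and 3 MSI1 knockdown libraries, with 1 point per library shaped by replicate number and a black bar for the mean and SD of the 3 libraries. MSI1 averages 13.8 in controls and 3.51 in knockdowns, and MSI2 averages 48.1 and 47.8.

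The largest rises included ACLY, TMEM65 and CA9, and the largest falls ZNF853, CXCL6 and PI15. ACLY, the enzyme that makes cytosolic acetyl-CoA for lipid synthesis (chromosome 17, 37276705 to 37328798), rose from 80.7 ± 18.2 to 577 ± 63.2 CPM, a log2 fold change of 2.84 (standard error 0.21, adjusted p = 0.00485). LPP, a LIM-domain protein of focal adhesions (chromosome 3, 189354357 to 190091153), rose from 73.7 ± 8.87 to 323 ± 24.98 (log2 fold change 2.13). PI15, a secreted peptidase inhibitor (chromosome 8, 75899327 to 75929819), fell from 345 ± 33.2 to 57.4 ± 5.35 (−2.59, adjusted p = 0.00358), and DCAF12, a substrate receptor of a ubiquitin ligase (chromosome 9, 34076381 to 34116771), fell from 156 ± 15.9 to 29.7 ± 2.43 (−2.39). The deepest fall was in the zinc finger gene ZNF853 (chromosome 7, 6622052 to 6630444), from 15.9 ± 4.38 to 1.03 ± 0.207 (−3.95, standard error 0.30). All SDs are over 3 libraries.

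The other genes with the largest rises were TMEM65 (log2 fold change 2.74), TMEM64 (2.35), the septin SEPT10 (2.33), the neuronal adhesion gene NEGR1 (2.15), FAM70A (2.02) and CA9, a carbonic anhydrase known as a hypoxia marker, which rose from 4.99 ± 0.908 to 31.2 ± 14.4 CPM (2.64, adjusted p = 0.0302). The other large falls were in the chemokine CXCL6 (−2.79), the Wnt ligand WNT7B (−2.44, from 36.7 ± 12.3 to 6.77 ± 0.446), the protocadherin PCDH20 (−2.12), the kinesin linker SYBU (−2.01) and TMEM2, a cell surface hyaluronidase (−1.97). These 16 genes were picked among those whose groups do not overlap. Groups that do not overlap were found in 3163 of the 13856 genes tested (22.8%, against 10% by chance).

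Over all genes tested, 232 genes changed at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 107 higher and 125 lower in the knockdown. With the replicate block the number of genes changed was 2398 (976 higher and 1422 lower), which contained all 232 with the same sign, and with DESeq2's size factors and the block it was 2278 (1163 higher and 1115 lower). With DESeq2's size factors in the unblocked test it was 191 (107 higher and 84 lower), DESeq2 called 798 (442 higher and 356 lower) and a fold limit of 1.5 left 37. Single libraries weighed heavily on the count. Without control replicate 1, 2 or 3 it was 10, 9 or 1028, and without knockdown replicate 1, 2 or 3 it was 0, 4 or 4, so that no gene named here kept its call without knockdown replicate 1. Among genes with a matched 3′ UTR, 41.5% of the 123 lower genes carried the word GCAGGAA there, against 16.5% of genes not called. TACATTT was carried by 68.3% of the 104 higher genes, against 27.5% of genes not called. Both words were picked for leading scores on the blocked log2 fold changes of the same libraries, so these shares are no separate test. The shares were not adjusted for 3′ UTR length. For single genes, any of the 3 leading words of a side was counted. These were GCAGGAA, AGCAGGA and TGCAGGA on the lower side, and TACATTT, ACATTTA and ATACATT on the higher side. Of the 8 largest falls, PI15, WNT7B, PCDH20 and TMEM2 carried a word of the lower side. ZNF853, CXCL6 and PI15 carried a word of the higher side, and DCAF12 and SYBU carried none. Of the 8 largest rises all but CA9 carried a word of the higher side, and TMEM65 and LPP also carried one of the lower side. Such words are common, as only 5545 of the 12668 genes with a matched 3′ UTR carried none of either side. The share of all genes with a word of 1 side was not counted, so these single genes show no excess.

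**Figure D2:**
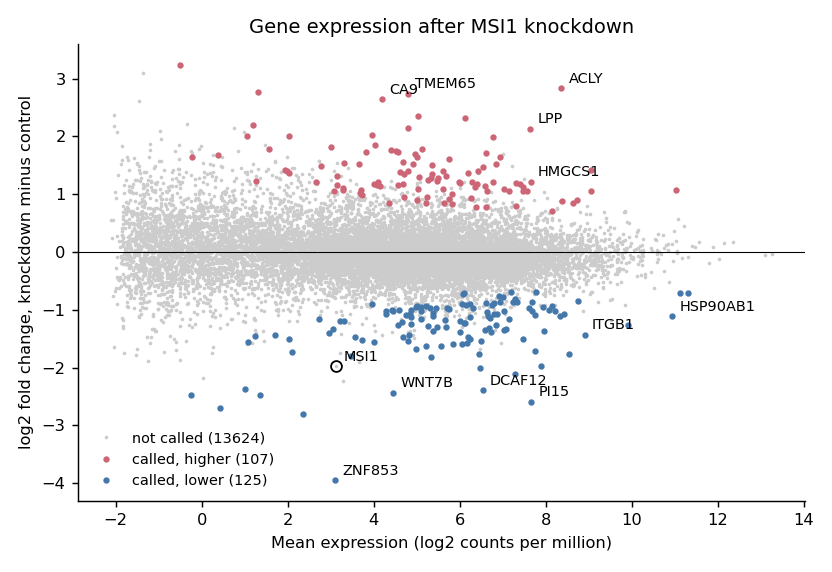
Log2 fold change of knockdown minus control (vertical axis) against mean expression in log2 CPM (horizontal axis), 1 point per tested gene, with 107 higher calls in red and 125 lower calls in blue. ACLY (2.84) and ZNF853 (−3.95) lie at the edges, and MSI1, circled at −1.97, is not called.

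Genes of cholesterol biosynthesis were higher as a group by limma's camera test with a preset correlation of 0.01 (adjusted p = 4.22e-09), but not with an estimated correlation (adjusted p = 0.630 with an estimated correlation) or by fry (adjusted p = 0.155). Of 25 tested members 3 rose and none fell, and adjusted over the list alone 5 were called, all higher. HMGCS1, an early enzyme of the mevalonate pathway (chromosome 5, 43325250 to 43349352), rose from 120 ± 11.8 to 280 ± 40.8 CPM (log2 fold change 1.21, adjusted p = 0.0164). SC4MOL, a sterol methyl oxidase, rose by 1.06 on the log2 scale, and INSIG1, a sterol-regulated brake on the pathway, by 0.85 (adjusted p = 0.0421). SQLE, squalene epoxidase, had a log2 fold change of 0.89 (adjusted p = 0.0567, and 0.00388 with the replicate block). The median of the list was 0.50. With the replicate block 15 members were higher and none lower.

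Extracellular matrix genes were also higher by camera (adjusted p = 4.32e-05), but not with an estimated correlation (adjusted p = 0.630 with an estimated correlation) or by fry (adjusted p = 0.292). Of 50 tested members 3 rose and none fell, and adjusted over the list alone 10 were called, 8 of them higher. VCAN, the proteoglycan versican, rose from 111 ± 14.6 to 242 ± 2.39 CPM (log2 fold change 1.12, adjusted p = 0.0149). NID2, a basement membrane nidogen, rose by 1.40 on the log2 scale. THBS1, thrombospondin, had a log2 fold change of −1.18 (adjusted p = 0.0583, and 0.00128 with the replicate block). With the block 18 members were higher and 2 lower. In the integrin and focal adhesion list, 1 of 45 tested members rose, CAV2 (1.12), a caveolin, and 2 fell. These were ITGB1, the beta 1 integrin chain (chromosome 10, 33229252 to 33287299), from 696 ± 192 to 258 ± 36.3 CPM (−1.43, adjusted p = 0.0302), and PTK2, the focal adhesion kinase (−1.02, adjusted p = 0.0300). There were 5 calls adjusted over the list alone, 3 higher and 2 lower, and with the block 12 members were higher and 5 lower. The list was higher by camera (median 0.17, adjusted p = 0.0405), with adjusted p = 0.630 with an estimated correlation, while its strongest calls were falls.

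The hypoxia and glycolysis list held 37 tested members, of which CA9 rose and EGLN3 fell. EGLN3, an oxygen-sensing prolyl hydroxylase, went from 85.4 ± 7.55 to 28.3 ± 2.96 CPM (log2 fold change −1.59, adjusted p = 0.00873), and PFKFB4, a regulator of glycolysis, had a value of 1.16 (adjusted p = 0.170, and 0.0238 with the block). There were 3 calls adjusted over the list alone, 2 of them higher, and 13 higher and 1 lower with the block. The list was higher by camera (median 0.29, adjusted p = 0.00146; adjusted p = 0.630 with an estimated correlation). None of the 51 ribosomal protein genes tested was called by edgeR, none adjusted over the list alone, and RPS25 came first with 0.32 (adjusted p = 0.345, and 0.0253 with the block, which called 2 of the list). As a group they were slightly higher (median 0.16, adjusted p = 0.00232; adjusted p = 0.664 with an estimated correlation). Genes of G1/S and DNA replication were lower as a group (median −0.16, adjusted p = 0.0405; adjusted p = 0.634 with an estimated correlation). Of 53 tested members only RFC5, a clamp loader subunit, was called, and it rose (0.84, adjusted p = 0.0354). There were 4 calls adjusted over the list alone, 3 of them lower. CDCA7 (−0.77, adjusted p = 0.0520) and the helicase subunit MCM3 (−0.54, adjusted p = 0.0765) missed the threshold, and with the block both were called among 16 lower and 2 higher members.

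These 6 lists were the ones past the threshold among 30 tested, and fry called none. With the replicate block camera called 8, adding the axon guidance and Eph/ephrin list (higher, adjusted p = 0.0621 without the block and 0.0155 with it) and the G2/M and mitosis list (lower, 0.0913 and 0.0170), and both had adjusted p = 0.616 with an estimated correlation and the block. Control replicate 3 stood apart from the other libraries, at 80.6 on a first principal component that held 62.5% of the variance. Without it 3 gene lists remained past the threshold. The adjusted p was 7.05e-07 for the named list cholesterol biosynthesis, and 0.00685 for the named list extracellular matrix and for the named list hypoxia and glycolysis. It was 0.227 for the named list integrins and focal adhesion, 0.146 for the named list G1/S and DNA replication and 0.0968 for the named list ribosomal proteins. The integrin list also missed the threshold without knockdown replicate 1 (0.121) or 2 (0.109), and the G1/S list without control replicate 1 (0.138), knockdown replicate 2 (0.111) or knockdown replicate 3 (0.0553).

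**Figure D3:**
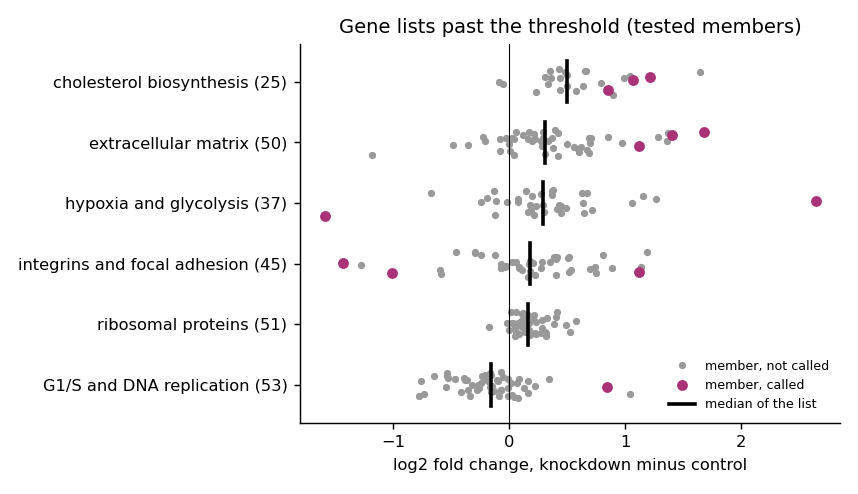
Log2 fold change of knockdown minus control (horizontal axis) of the tested members of the 6 lists past the threshold, 1 point per gene, with called genes in purple and a black bar at the median of each list. The medians run from −0.16 in G1/S and DNA replication to 0.50 in cholesterol biosynthesis.

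Several genes of signalling, cell death and stem cell identity changed in lists that did not pass as a whole. In the Wnt list 3 of 36 tested members fell, WNT7B, WNT5A (log2 fold change −0.81, adjusted p = 0.0362) and the transcription factor LEF1 (−1.12, adjusted p = 0.0372), and none rose, with 5 calls adjusted over the list alone, and with the block 10 were lower and 5 higher. Among 35 apoptosis regulators 3 fell and none rose, the death-promoting genes PMAIP1 (−1.47, adjusted p = 0.0330) and BCL2L11 (−0.94, adjusted p = 0.0354) and the caspase inhibitor XIAP (−1.11, adjusted p = 0.0336). There were 4 calls adjusted over the list alone, 8 lower and 3 higher with the block, and the median of this list was 0.04 with a mean of −0.11 and a lower direction by camera (adjusted p = 0.794). PMAIP1 was also the only call among 29 p53 targets, with 2 called adjusted over the list alone, and 4 lower and 3 higher with the block. Of 25 neural and glioma stem markers the factors SOX4 (−0.90, adjusted p = 0.0300) and SOX2 (−0.76, adjusted p = 0.0432) fell, and 6 were called adjusted over the list alone, 4 of them lower, while the block gave 10 lower and 4 higher.

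Among 12 Musashi targets taken from earlier literature, TGFBR1, a TGF-beta receptor, rose from 21.3 ± 5.40 to 60.2 ± 9.78 CPM (adjusted p = 0.0300) and SMAD3, which transmits its signal, fell from 439 ± 59.4 to 203 ± 38.9 (−1.11, adjusted p = 0.0346). The list had 3 calls adjusted over the list alone, and with the block 1 member was higher and 2 lower. NUMB, a Notch antagonist often named as a Musashi target, had a value of −0.25 (adjusted p = 0.461). TGFBR1 was the only call among 35 TGF-beta and YAP targets, of which 10 were called adjusted over the list alone, and 8 were higher and 4 lower with the block. In the immediate early and ERK feedback list of 38 tested members ETV1 (1.62) and the growth factor HBEGF (1.54) rose, with 6 called adjusted over the list alone, and 7 higher and 5 lower with the block. Each of 6 further lists held 1 call, and adjusted over the list alone they held 1 to 5. With the block, calls higher and lower were 5 and 5 for matrix proteases, 2 and 5 for interferon response, 11 and 8 for cell-cell junctions, 8 and 5 for axon guidance, 2 and 4 for NF-kB targets, and 6 and 10 for the unfolded protein and amino acid response. TIMP3, a protease inhibitor, rose among 27 matrix proteases and inhibitors (1.79), and IFI44L rose among 42 interferon response genes (1.10). CADM1 fell among 44 cell-cell junction genes (adjusted p = 0.0340), PLXNA2 among 45 axon guidance genes (−1.36), CXCL3 among 25 NF-kB targets (−2.47) and CHAC1 among 36 unfolded protein and amino acid response genes (−1.81).

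No member was called in the lists of G2/M and mitosis, Notch pathway, splicing and RNA-binding factors, oxidative phosphorylation, lysosome and autophagy, histones, or markers of neurons, astrocytes, oligodendrocytes, leukocytes, endothelium and fibroblasts. Adjusted over the list alone 3 were called among 11 astrocyte markers and 1 each among 13 neuron and 5 endothelial markers, and none in the other 9 of these lists. With the block 9 of the 53 G2/M and mitosis genes were lower, and calls higher and lower were 1 and 2 for Notch, 2 and 6 for splicing, 0 and 4 for oxidative phosphorylation, 3 and 4 for lysosome, and 1 and 0 for histones. They were 2 and 0 for neurons, 2 and 2 for astrocytes, 2 and 1 for oligodendrocytes, 1 and 0 for endothelium, 3 and 1 for fibroblasts, and 0 for leukocytes. Camera's adjusted p for the lists that did not pass ran from 0.0621 to 0.875. The leukocyte list, with 4 tested members, was too small for it. The direction by camera was higher for the NF-kB list, whose median was −0.07 and mean −0.06. The Notch list had a median of −0.03 and a mean of 0.04, and the histone list a median of 0.09 and a mean of −0.003. The lysosome list was higher by camera with a median of −0.01.

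No exon passed the threshold when each exon was tested against the other exons of its gene. Of 123109 exons in 11227 genes, edgeR's diffSpliceDGE called 0, with 263 at an unadjusted p below 0.05, and by gene 0 were called from Simes p-values, with 14 at an unadjusted p below 0.05, and 4 by an F test. The lowest p belonged to the last exon of ZAK, a stress-activated kinase, described here after its values were seen. This exon of 1960 nucleotides, the last of 21 (chromosome 2, 173839024 to 173840983), made up 14.1 ± 0.78% of the exon counts of ZAK in controls and 5.01 ± 1.28% in knockdowns (SD, n = 3), a log2 change of −1.04 relative to the gene with an adjusted p of 0.120 by edgeR. Exon 12, of 5996 nucleotides (173794124 to 173800119), made up 47.01 ± 0.62% in controls and 68.6 ± 1.20% in knockdowns, and limma's diffSplice gave it an adjusted p of 0.0554.

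With the replicate block 10 exons in 5 genes were called, and 4 genes by Simes p-values, and these too were chosen after their values were seen. Of these 10, 6 lay in ZAK from exon 15 to exon 21, all lower, with an adjusted p of 1.49e-09 for the last exon. The others were exon 4 of BTBD7 (−0.88 relative to the gene, adjusted p = 0.000687), exon 4 of TPM1, a tropomyosin (0.92, adjusted p = 0.00535), exon 13 of ANTXR1, an anthrax toxin receptor (0.70, adjusted p = 0.0214), and exon 2 of the dynein light chain gene DYNLL1 (0.99, adjusted p = 0.0336). The groups overlapped for TPM1 and DYNLL1, and DYNLL1 exon 2 had only 10 counts in control replicate 3 and 59 in knockdown replicate 3. Without the block limma's diffSplice called 2 exons, the same exon of BTBD7 (chromosome 14, 92823727 to 92824806, adjusted p = 0.0110) and exon 3 of JAKMIP2 (chromosome 5, 147020704 to 147021201, adjusted p = 0.00270), both lower. In simulated exon counts the blocked test made 55 false calls, 33 of them in genes without any change. Without control replicate 3 the unblocked test called 1 exon.

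**Figure D4:**
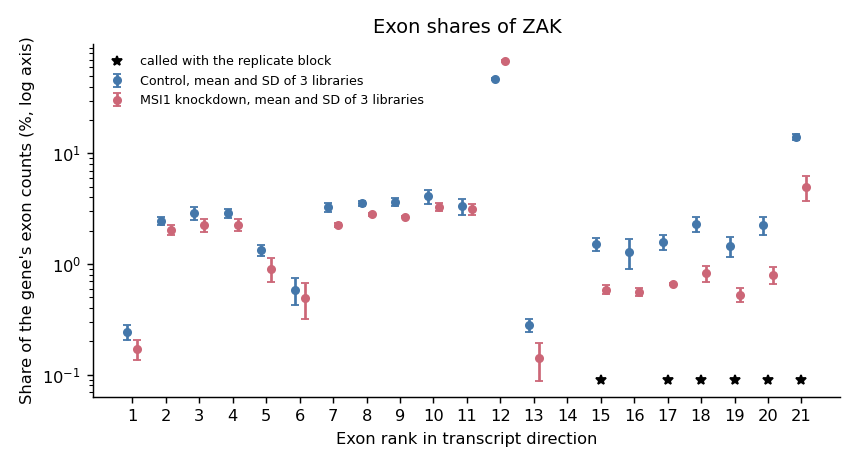
Share of the exon counts of ZAK in percent (vertical axis, logarithmic) for each tested exon in transcript order (horizontal axis), with points for the mean and bars for the SD of 3 control or 3 knockdown libraries, and stars for exons called with the replicate block. Exon 12 averages 47.01% in controls and 68.6% in knockdowns, and exon 21 averages 14.1% and 5.01%, while exon 14 was not tested.

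Positions found in all 3 MSI1 iCLIP lists were denser in last exons than in introns. A large share of those in exons lay in a few abundant transcripts. There was no control iCLIP sample, so whether MSI1 bound each position was not tested. The 3 iCLIP lists shared 4446 positions, 3.05% of the shortest list. Of these, 45.9% lay in exons, 35.5% in last exons, which hold most 3′ UTR sequence, 31.6% in introns and 22.4% opposite a gene. In the single lists 13.8%, 18.6% and 24.5% of sites were exonic and 82.0%, 69.3% and 66.3% intronic, in replicates 1, 2 and 3. Per kilobase, last exons held 42.4 times as many shared sites as introns, and 22.03 times for shared sites with a p below 0.05 in each list. For the whole lists of replicates 1, 2 and 3 it was 4.47, 7.87 and 11.5 times. Against internal exons the ratio was smaller, 14.77 for shared sites and 4.81 for those with a p below 0.05 in each list. For the whole lists of replicates 1, 2 and 3 that ratio was 3.06, 5.66 and 6.65. Within genes 3445 positions were shared, against 42.3 ± 6.4 (SD) after 100 shuffles of sites within their genes and 225.5 ± 12.5 after shuffles within their exon or gene, and none of the 100 shuffles reached the observed number (permutation p = 0.0099, the smallest that 100 shuffles can give). Without iCLIP replicate 1, 2 or 3 the remaining pair shared 10664, 28425 or 12788 positions. The lists reach a p-value of 1, and 213 positions had a p below 0.05 in each list, of which 41.8% lay in introns and 24.4% in last exons.

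The exonic shared sites fell in 394 genes, and 10 of these held 51.2% of the 2049 sites. The number of sites rose with expression (Spearman rho 0.365 across the iCLIP genes tested). SCD, the desaturase that makes monounsaturated fatty acids (chromosome 10, 102096762 to 102114578), held 264, of which 263 were in its last exon, and CD44, the hyaluronan receptor (chromosome 11, 35116993 to 35210525), held 257, all in the last exon. The nuclear noncoding RNA MALAT1 (chromosome 11, 65021809 to 65030513) held 180 and ADAM19, a membrane metalloprotease (chromosome 5, 156836890 to 156935346), 64. Others among the 10 were ARL6IP1 with 35, the noncoding RNA NEAT1 with 33, the galactosyltransferase B4GALT1 with 31, the desaturase FADS2 with 29 and ITM2B with 25. MALAT1 was the only one of the 10 whose expression changed, a log2 fold change of −0.71 (adjusted p = 0.0462), and the named gene MALAT1 had an adjusted p of 0.0704 under DESeq2's size factors. SCD was at 0.23 (adjusted p = 0.641), CD44 at −0.19 (0.514) and NEAT1 at −0.86 (0.0548). With the replicate block NEAT1 (adjusted p = 0.00223), ARL6IP1 (0.0114), B4GALT1 (0.0339) and FADS2 (0.0435) were also called.

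**Figure D5:**
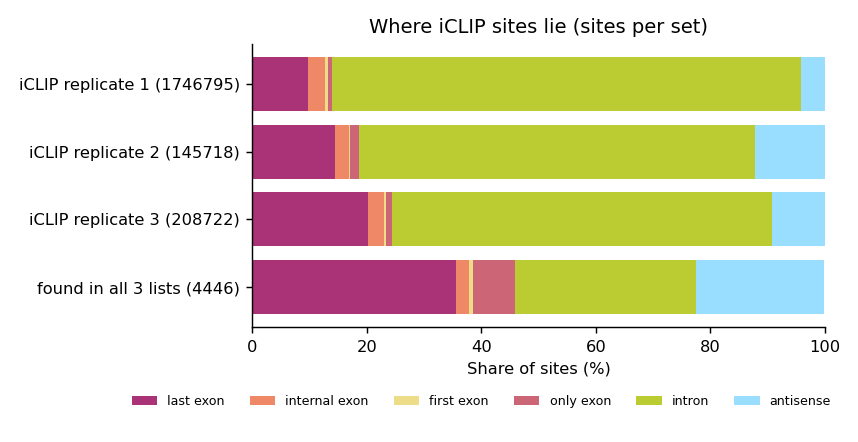
Share of iCLIP sites in percent (horizontal axis) by the kind of gene region for the lists of replicates 1, 2 and 3 and for the 4446 positions found in all 3 lists. Last exons take 9.73%, 14.5% and 20.2% of the single lists and 35.5% of the shared positions.

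Genes that carried an exonic shared site and changed with the knockdown numbered 14 of 232. Those that rose included the homeobox gene HOXB3 (log2 fold change 1.18), IGFBP5, which binds insulin-like growth factors (1.43, from 287 ± 84.3 to 771 ± 30.9 CPM), CLIC4 (1.05) and SYTL4 (1.05). Those that fell included B4GALT5, a galactosyltransferase (−1.33), the chaperone HSP90AB1 (−1.11, from 2687 ± 154 to 1241 ± 138), the zinc transporter SLC39A14 (−1.03), ITGB1 (−1.43) and TTPAL (−0.92). Each of these 9 held between 1 and 4 shared sites, with 4 in CLIC4 and in SLC39A14, while others among the 14 held more, 180 in MALAT1, 15 in MAP1B (−0.70) and 6 in CDK2AP1 (0.71), the last pair chosen after their values were seen. HSP90AB1 and the ribosomal protein genes have near-identical copies elsewhere in the genome, and how reads shared with those were counted is not given in the sources used here, so their values are uncertain.

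Compared with 10000 random gene sets matched on expression and exonic length, iCLIP genes made up more of the changed genes by a margin that missed the threshold. The 14 genes compare with 8.70 ± 2.68 (SD) in matched sets, a ratio of 1.61 (two-sided permutation p = 0.0614), with 1.75 among higher genes (p = 0.141) and 1.52 among lower genes (p = 0.226). With the replicate block the ratio was 1.20 (102 genes, permutation p = 0.0263). It was 1.68 among higher genes (permutation p = 0.0001, the smallest that 10000 sets can give) and 0.95 among lower genes (p = 0.689). The 344 tested iCLIP genes had a median log2 fold change of −0.03, against −0.07 in matched sets, a difference of 0.05 (permutation p = 0.0101). That difference missed the threshold without control replicate 3 (p = 0.352), and camera gave p = 0.718 for the same genes, and p = 0.831 with an estimated correlation. None of the 10 exons called with the block had a shared site within 500 nucleotides. Matched exons gave an average of 0.0112, too few for a lack of sites to show. Of the 44 exons called by limma's diffSplice with the block 0 had one, against 0.794 (permutation p = 0.634). A site found in at least 2 lists lay within that distance of 7 of the 44, against 6.18 (permutation p = 0.800). Without the block edgeR called no exon, so the comparison has no value there.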

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

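The count of sites opposite to genes was made only after the lists were examined. Of the 4446 positions found in all 3 iCLIP lists, 997 (22.4%) lay only on the strand opposite to a gene, a signal in data that no comparison above uses. They lay opposite 626 genes, with 102 of them (10.2%) opposite the 5 leading genes and 50 opposite BTRC, on chromosome 10 between 103114635 and 103114737. In the single lists 4.22%, 12.2% and 9.28% of sites lay opposite to genes, in replicates 1, 2 and 3. No explanation was tested.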

How the results depend on the processing

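Tests that leave out both libraries of replicate 3, that add the block to DESeq2, its size factors, limma's diffSplice, fry, the estimated correlation or the 2-list sites, and those on sites with p below 0.05 or within 5 nucleotides, were chosen only after the results were seen. The MSI1 transcript kept its direction throughout, between −1.69 and −2.35 with single libraries left out, and passed the threshold with DESeq2 (−1.92), the replicate block (−1.97), both libraries of replicate 3 left out (−1.99, or −2.01 with the block) and with the block in DESeq2 or with its size factors (−1.92 each). Its adjusted p ran from 0.0608 to 0.0742 under other filters, DESeq2's size factors and limma-voom, and from 0.000372 to 0.306 with 1 library left out. The number of genes changed, 232, was 798 with DESeq2, 2398 with the replicate block, 37 with a fold limit of 1.5, 1699 without both libraries of replicate 3, 4456 there with the block, 2683 with DESeq2 and the block and 2278 with its size factors and the block. With single libraries left out it ran from 0 without knockdown replicate 1 to 1028 without control replicate 3, with 4, 4, 9 and 10 without knockdown 2, knockdown 3, control 2 and control 1. It stayed between 191 and 258 under the other filters, size factors and limma-voom. The block lowered the biological coefficient of variation from 0.254 to 0.136. Beyond fewer libraries, and fewer residual degrees of freedom, the cause was not tested. Of the 54 called genes picked by the naming rule, 54 kept their call with DESeq2, with the block and without control replicate 3, and 45 with DESeq2's size factors. Without control replicate 1 or 2 the numbers were 8 and 7, without knockdown replicate 1, 2 or 3 they were 0, 4 and 4, and none reversed.

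For gene lists, the 6 calls fell to 0 with an estimated correlation, to 0 with fry, and to 0 for both of these with the replicate block, while 5 were called without a filter, 4 with at least 1 CPM in 3 samples and 4 without replicate 3, which lost the integrin list, and in the last 2 settings the G1/S list, and the number ran from 3 without control replicate 3 to 8 without control replicate 2. For exons changed, 0 in the unblocked test, 2 were called with limma's diffSplice, 10 with the block, 44 with limma and the block, 7 without replicate 3 and 33 there with the block, and from 0 to 1 with single libraries left out, 1 being without control replicate 3. Genes with exon changes numbered 2, 4, 29, 3 and 24 in these settings, 4 by the F test, and from 0 to 1. The shared iCLIP sites, 4446, were 1512 for the sites at or below the median p of each list, 213 at p below 0.05, 15041 within 5 nucleotides and between 10664 and 28425 with a list left out. A reciprocal overlap means nothing for single nucleotides.

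The difference in median of CLIP genes and expression change, 0.045, no longer passed with the sites at or below the median p of each list (0.021). Nor did it pass with any site in the gene span (0.010), no matching (0.012) or sites with p below 0.05 in 2 lists (0.046). It ran from 0.016 without control replicate 3 to 0.076 without control replicate 2 or knockdown replicate 3. The ratio of CLIP genes among changed genes, 1.61, passed the threshold with sites in 2 lists (1.25), the block (1.20), no matching (2.44), 2 lists and the block (1.09), and the block without replicate 3 (1.20), and with single samples left out ran from 1.25 without iCLIP replicate 1 to 1.48 without control replicate 3, passing there and without iCLIP replicate 2 (1.32) or 3 (1.34). Among higher genes those values were 1.51, 1.68, 2.27, 1.40 and 1.41, and from 1.5 without control replicate 3 to 1.96 without iCLIP replicate 3. Among lower genes the ratio, 1.52, turned below 1 with the block (0.95), with 2 lists and the block (0.94), without iCLIP replicate 1 (0.88) and without iCLIP replicate 3 (0.95), was 2.59 without matching and 1.45 without control replicate 3. The cause was not tested. Settings with fewer than 1 expected gene give no ratio, a limit set after the values were seen. By the F test, genes with exon changes numbered 14 with the block and 4 without it.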

Other observations

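Chosen after the results were seen were the tests of gene lists among iCLIP genes, of the word that goes with higher values, of a condition shared by both libraries of replicate 3, and of the other splits for genes and gene lists and with the block. Of 30 gene lists tested, 5 held more genes with shared MSI1 sites than matched random lists, and 2 of these are given here. Of 45 tested integrin and focal adhesion genes, 8 carried an exonic site found in all 3 lists (ACTN4, CD151, ITGA3, ITGAV, ITGB1, ITGB8, TNS3 and VCL), against 2.79 in matched random lists (one-sided permutation test, adjusted p = 0.0420). Of 25 NF-kB targets and cytokines 3 did (CCL2, IL11 and LIF, against 0.43, adjusted p = 0.0426). Cell-cell junctions, with 4 of 44 against 2.0, did not pass (adjusted p = 0.347). Ribosomal protein genes carried 1 against 5.24 and genes of G1/S and DNA replication 0 against 1.85.

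Over 12668 tested genes, called or not, the word GCAGGAA in 3′ UTRs went with lower log2 fold changes (score −12.34, against −4.89 for the lowest of 14550 words in 100 shuffles) and TACATTT with higher ones (score 17.61, against 4.94), after adjustment for 3′ UTR length, GC content and expression, without which genes with TACATTT had a median of −0.03 and those without it −0.02. A seed match to a small RNA used for the knockdown, and to another in the control libraries, are candidate explanations that passed these tests, as hypotheses, since the labels do not say how either group was treated and title the controls WT, which names no small RNA in them. Sequence composition of the genes cannot be told apart from the former, because GCAGGAA also scored −6.46 in coding sequence, although its shifted forms AGCAGGA (−3.74) and TGCAGGA (−1.74), and TACATTT (2.48), scored nearer 0 there. MSI1 binding at the changed transcripts passed its test as well, with a ratio of 1.20 to matched sets in the blocked test. However, 102 of its 2398 called genes carried a shared site, and 713 an exonic site found in at least 2 lists (ratio 1.09). The latter ratio was 1.40 among higher genes (permutation p = 0.0001) and 0.94 among lower genes (permutation p = 0.0436). Of all 13856 tested genes, 344 and 2620 carried these sites. Among 5545 genes without the leading words, the shared-site ratio was 1.71 for higher (permutation p = 0.0559) and 1.05 for lower genes. There the 2-list sites gave 1.42 (permutation p = 0.0002) and 0.87 (permutation p = 0.0478). An effect of lost MSI1 on genes without such sites stays open. For GTAG, TAGT and ATAG, density in 3′ UTRs and blocked log2 fold change had a Spearman rho of −0.033, −0.025 and −0.017. Both were first adjusted for 3′ UTR length, GC content and expression, over all 12668 genes.

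Control replicate 3 lay far from the other libraries, at 80.6 on a first principal component with 62.5% of the variance. Fragmented RNA cannot be told apart from other explanations: its ratio to the other controls rose with exonic length (Spearman rho 0.202 across genes) where loss of long transcripts needs a fall, but its last-exon share of 36.25% (other controls 32.72% and 32.14%) and first-exon share of 1.19% (2.29% and 2.4%) go the way of degraded RNA. Knockdown material alone would put this library between the other controls (−12.9 and −19) and the knockdowns (−18.1, −40.9 and 10.4) on the first component. Its 80.6 lay outside both groups, which argues against such material as the whole explanation. That component did not part the groups, while the second, with 22.8% of the variance, did. There control replicate 3 lay at 3.9, between the other controls (29.1 and 31.2) and the knockdowns (−17.4, −16 and −30.8), where a part of knockdown material would put it. The median share of the way from the other controls toward the knockdowns was −0.239 for falling genes (quartiles over genes −0.924 and 0.777). It was 0.146 for rising genes (quartiles −1.173 and 0.841) and 0.567 for MSI1. On the knockdown side lay 41.5% of falling and 54.3% of rising genes. A part of knockdown material cannot be told apart by these values. Both tests met bounds set in advance for arguing against these explanations (a rho of at least −0.1, a share of at most 0.1), which were set aside after the values were seen because of these exon shares and quartiles. A condition shared by both libraries of replicate 3 may account for it, since their ratios to the other replicates had a rho of 0.85 across genes, and no biological explanation was tested, as the labels give none.

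With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 232 genes and the highest of the others 0, so 1 split was as large, and with the replicate block the real split called 2398 and the 3 others that part all pairs called 0. For gene lists the real split called 6 and the highest other 10, and 4 splits called as many. For exons, and for genes with exon changes, the real split called 0 and the highest other 1, so all 10 were as large. With the block the real split called 10 exons and the 3 others that part all pairs called 0.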
